A study of Arabidopsis thaliana with 24 samples.

How the data were processed

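Total RNA was taken from floral buds of at least 4 inflorescences per sample, per the labels' protocols. Per the submitters' processing notes, the tools named are STAR 2.5.3a and RSEM 1.3.0 and the genome build is TAIR10. What each tool was used for is not given in the sources used here. The deposited table pairs each gene's code, name and type with 24 columns of values.

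The labels give every sample a group, and the names of the value columns were compared with all label fields of the 24 samples and with the series text. The column names are laboratory codes of another kind than those in the sample titles, and 0 of 24 matched. Assigning columns by their order or by the expression of genes such as AP1 was ruled out beforehand. The reason was that an error could put values under the wrong group. All 24 value columns were therefore left out of the results. The ranges and totals of the columns and a few rows were viewed when the table was opened, and no test was run on them.

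The gene column alone was used. Locus codes were matched to the RefSeq gene table of assembly TAIR10.1, in which 32548 of the 32833 codes have an entry, and no coordinates were taken from it. The 19 gene lists were written before the data were examined, each gene with its code and a name. A list name counted as matching where RefSeq gives it to the same code as symbol or synonym, ignoring case, hyphens and spaces. This held for 351 of the 359 distinct genes. For the other 8 the code was kept, and the planned lookup of the name under another code was not run. PIF8, for instance, is called UNE10 in both tables. Others, such as A9 and RVE6, carry the list name in the deposited table but not in RefSeq. The planned tests of differential expression, gene lists and overlap, the alternatives planned for them, and the rule for naming genes by their change were not applied, since each needs columns assigned to groups.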

Results

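Gene expression was profiled by RNA sequencing in floral buds of Arabidopsis thaliana, in 24 samples that the labels place in 8 groups of 3. Wild-type (Col-0) plants gave 15 samples in 5 groups, taken at 0 h in white light, after 1, 3 and 24 h of simulated shade, and after 24 h in white light. The MB2 line gave 9 samples in 3 groups, taken at 0 h in white light and after 24 h in white light or in shade. MB2 carries APETALA1 (AP1), a MADS-domain regulator of floral meristem and organ identity, fused to a glucocorticoid receptor domain under the AP1 promoter. Its background lacks functional AP1 and its close relative CAULIFLOWER (CAL), so that dexamethasone starts flower formation. Dexamethasone was given at 2 µM, 3 days before shade. For every group the day length given is 16 h of light and 8 h of dark. Shade was white light with added far-red light, which lowered the red to far-red ratio from 3.0 to between 0.05 and 0.06. Photosynthetically active radiation is given as 100 µmol per square metre per second for every group, in white light and in shade.

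The design implies a time-matched comparison of shade with white light at 24 h in each genotype, and the test of whether that shade effect differed between genotypes. It also implies comparisons of 1 h and 3 h of shade with the 0 h wild-type samples, in which light and time of day are confounded, since the controls were taken earlier. The passage of a day in white light and the difference between MB2 and wild type at 0 h complete the set. In MB2 that day began 3 days after dexamethasone, so the day in white light and the progress of flower formation are confounded. The labels name dexamethasone for MB2 alone. Genotype and dexamethasone are therefore confounded in the difference at 0 h and in the test of shade between genotypes. Bud stage cannot be separated from them in either. Dexamethasone was to start flower formation in MB2 3 days before shade, and no such start is given for wild type. The plan described the MB2 buds as synchronised early floral buds. None of these comparisons is reported here. The count table has 24 columns of values, and 0 of the 24 column names occurred in the labels of any sample. Only the label fields and the series text used here were searched for a key to the column names. Within these sources, the columns could be assigned to groups only by their order or by their values, and neither was done. No expression level, fold change or count of changed genes is given, and the depth of each group is not stated for the same reason.

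The identities of the genes in the table could be examined without the value columns. The table lists 32833 genes by locus code. By the type the table gives, 27628 are protein-coding, 2444 lncRNA (long non-coding RNA), 1037 atlncRNA, 689 tRNA and 325 miRNA. The remainder are in smaller types. A gene name accompanies 13124 of the codes. All 359 distinct genes of the 19 lists fixed for these comparisons have a row in the table. The early shade-induced regulators, among them the homeodomain-leucine zipper gene ATHB2 and the bHLH genes HFR1 and PIL1, have 23 of 23 members listed. The auxin response list has 31 of 31 members, the floral organ identity list 17 of 17, the gynoecium and ovule list 19 of 19 and the circadian clock list 23 of 23. A listed gene is one that has a row, which says nothing about whether it was expressed in floral buds. With 27628 protein-coding genes in the table, full coverage of the lists was largely fixed in advance. It checks the codes and is no result about the lists.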

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

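The alternatives below were chosen after the table had been seen. Searching the label text for the digits of each column name alone also matched 0 of 24 columns. A search for the whole name with case ignored gave 0 as well. That search could add little, since the main comparison also ignored case and had found no name in the sample labels or the series text. By code, 359 list genes had a row in the table. For 262, the list name occurs among the names that the table gives, without a check that the code is the same. RefSeq gave 351 of the list names to the same code as symbol or synonym, and 296 as symbol alone. The alternatives set out beforehand for tests of expression were not run, because no column was assigned to a group. No paired analysis was possible because no value column was assigned to a sample and the labels carry no replicate numbers. The numbers used to name the samples within a group follow the order of the records and pair nothing.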
